A study of Homo sapiens with 15 samples.

How the data were processed

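Small RNA was measured in 15 sequencing libraries of extracellular samples from DiFi, an established colorectal cancer cell line. Per the labels' protocols, RNA was extracted with a miRNeasy kit and made into libraries with a NEXTflex small RNA kit. The sample names place the libraries in 6 groups, named by a pool number and a preparation. The labels do not define pool or media, do not say which isolation method belongs to which name, and do not say whether replicates come from separate cultures. All p-values therefore measure only the spread between these samples.

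The deposited table holds expected counts per mature miRNA, per the file headers and the values themselves, with 1070 features. Of its 16050 values, 771 (4.80%) were not whole, in 124 features, and 5 features hold several merged miRNA names. Per the submitters' processing notes, cutadapt 2.10, Bowtie 1.3.1, FastQC and build GRCh38 were used. The roles of these tools, the counting program, the mismatch setting and the annotation release are not given in the sources used here. The counts were rounded to whole numbers before testing. Counts that sequence-similar family members could share, such as those of let-7, miR-29, miR-200, miR-320 or miR-30, are uncertain between members.

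Counts were compared with edgeR 4.0.16 (R 4.3.3) using the quasi-likelihood test with robust estimation, TMM scaling and filterByExpr by group, which left 306 miRNAs holding 99.98% of the counts. All 15 libraries entered 1 fit of 6 group means without a replicate block, so groups of 2 or 3 libraries share an estimate of the spread. The common dispersion was 0.187, a biological coefficient of variation of 0.432. The 8 comparisons were exomere minus media in pools 1 and 2, supermere minus media in pool 3, pool 2 minus pool 1 exomere, the 3 differences between media groups, and pool 3 supermere minus pool 2 exomere. A further contrast tested the exomere-minus-media difference of pool 2 minus that of pool 1. Adjusted p-values are Benjamini-Hochberg values over the 306 miRNAs of a comparison, with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the test's F statistic. Levels are TMM-normalised CPM, given as mean and standard deviation (SD) over libraries.

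These choices, with the lists and the rule for naming miRNAs, were made before the data were examined. The rule named, per comparison, up to 10 miRNAs with the largest rise and 10 with the largest fall past the threshold whose mean CPM over the compared groups was at least 100. It also named the 10 most abundant miRNAs and miR-1246. Examples from a list are its up to 4 members with the highest mean CPM. The 10 lists were the let-7 family, the miR-17~92 cluster and its paralogs, the miR-200 family, miRNAs of colonic epithelium and colorectal cancer, entries that share sequence with other abundant RNAs, blood cell and endothelial miRNAs, miRNAs of other tissues, the miR-10, miR-99/100 and miR-125 families, the miR-26 and miR-30 families, and the miR-320 family. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the 10 lists of a comparison. The adjusted p given for a list is camera's.

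Totals ran from 364426 to 12743545 counts per library. Intervals for shares of single libraries are 95% exact binomial intervals and cover counting error only. Per library, a count of 0 allows up to 3 counts. Counting intervals of ratios pool the counts of a group and come from the exact binomial interval. They cover counting error only, so their bounds do not allow for the spread between libraries. Library composition was compared with two-sided exact permutation tests, 40 in all, and richness was rarefied to 364426 counts. Positions of miRNAs in the table were compared with GENCODE 29, where 346 of 353 positions of tested miRNAs matched a miRNA gene.

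The code was tested on simulated counts of the 1070 features with 200 changed in each run. All shares given are of miRNAs that passed the low-count filter, and changed miRNAs that it removed are not counted. At 4-fold those that passed numbered 87 to 112 per comparison over 5 runs. Of these, 48.2% were recovered for exomere minus media in pool 1 and 59.2% for that in pool 2. The share was 37.9% for supermere minus media, 53.7% for pool 2 minus pool 1 exomere, and 42.7% for supermere minus pool 2 exomere. For changes of 2-fold the recovered shares were 7.14%, 19.4%, 6.58%, 12.0% and 7.07%, and for 8-fold 73.7%, 71.4%, 60.2%, 72.4% and 70.8%. Between 0.414% and 0.579% of the unchanged miRNAs that passed the filter were called. The simulated libraries took their scale from the TMM factors of the data, and rises and falls were equal in number. These shares therefore hold where TMM scaling is right, and the runs did not test the choice of scaling. For pool 2 exomere minus media, camera called a let-7 list lowered 4-fold in 10 of 10 runs, and called any list in 1 of 10 runs with nothing changed. The simulated miRNAs varied independently, while the correlations estimated for the real lists were 0.147 (miR-26 and miR-30) to 0.814 (miR-320). These runs therefore cannot show how often camera calls unchanged lists of correlated miRNAs.

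Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means. The 3 correlations between pool 1 and pool 2 exomere libraries were 0.31, 0.11 and 0.10, all above the 0.1 set as the minimum, so the numbers were taken to pair those libraries by the rule set in advance, although the deviations of pool 2 exomere replicate 2 matched a pool 1 exomere library of another number better. Same-numbered media libraries of different pools were also above that minimum, at 0.14 to 0.29. So was the number shared by supermere and pool 3 media (0.15). The pairing of exomere libraries comes from the data, since the labels give no meaning to the numbers.

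The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, DESeq2 size factors, scaling to the total count with and without the most abundant miRNA, no low-count filter, a stricter filter (10 CPM and 10 counts in 2 libraries), an additive or nested replicate block, only the groups compared, an estimated inter-gene correlation in camera, and each library left out. Chosen after the data were seen were the removal of a GC trend from list medians, the omission of both exomere libraries numbered 1, the other scalings of list medians, total-count values relative to the median miRNA, and thinning to equal counts outside miR-1246. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. No library was left out of the main tests.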

Results

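Mature miRNAs were counted in 15 small RNA libraries of extracellular material from DiFi, an established colorectal cancer cell line. The series tests 2 methods for isolating secreted carriers of extracellular RNA. Exomeres and supermeres are secreted nanoparticles that lack a membrane. The groups were pool 1 exomere (n = 3), pool 1 media (n = 2), pool 2 exomere (n = 3), pool 2 media (n = 3), pool 3 media (n = 2) and pool 3 supermere (n = 2). Pool 1 and pool 3 media hold the libraries numbered 1 and 2, and pool 3 supermere holds those numbered 2 and 3. Pool 3 is the only pool with supermere libraries and has no exomere libraries, so the carrier and the pool cannot be separated between those groups. The total count was 4865506, 1144284 and 364426 in the pool 1 exomere libraries and 785884 and 1406496 in pool 1 media. It was 5446943, 948513 and 598666 in pool 2 exomere and 4877156, 8506375 and 12743545 in pool 2 media. It was 563488 and 827386 in pool 3 media, and 5061760 and 455522 in pool 3 supermere.

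miR-1246 was the most abundant miRNA in every group and took 44.4% (95% interval 44.3 to 44.5) to 97.5% (97.5 to 97.5) of the counts of a library. Its mean share was 69.7% ± 22.4 (SD, n = 3) in pool 1 exomere, 64.9% ± 23.0 (n = 2) in pool 1 media and 72.6% ± 23.1 (n = 3) in pool 2 exomere. It was 95.7% ± 2.33 (n = 3) in pool 2 media, 53.9% ± 13.4 (n = 2) in pool 3 media and 70.6% ± 5.43 (n = 2) in pool 3 supermere. The deposited table places its sequence, AATGGATTTTTGGAGCAGG, on chromosome 2 at 176601024 to 176601042 (GRCh38, minus strand), in MIR1246. The same sequence occurs unchanged in 7 annotated genes with U2 small nuclear RNA names, so its counts cannot be assigned to the miRNA gene alone. These genes include RNU2-1, but also RNU2-33P, RNU2-37P, RNU2-48P and RNU2-61P, whose names mark pseudogenes. The share was higher in all 3 pool 2 media libraries than in both pool 1 media and both pool 3 media libraries, with an exact permutation p of 0.1 in each case, the smallest those designs allow, and 0.5 after adjustment over 40 composition tests. The other 6 comparisons of the share gave exact p-values of 0.3 or more. For supermere minus media of pool 3 the exact p was 0.333, also the smallest that design allows. Both supermere libraries (74.4% and 66.7%) lay above both media libraries (63.4% and 44.4%), so that value does not show that the share was alike. The 10 most abundant miRNAs of a library together took 89.1% ± 7.68 in pool 1 exomere, 81.4% ± 12.5 in pool 1 media, 91.3% ± 7.50 in pool 2 exomere, 98.4% ± 0.64 in pool 2 media, 85.7% ± 5.85 in pool 3 media and 93.1% ± 1.89 in pool 3 supermere. In the same order, the effective number of miRNAs (the exponential of the Shannon entropy) was 6.35 ± 4.39, 9.15 ± 8.24, 5.37 ± 4.35, 1.38 ± 0.20, 9.14 ± 4.41 and 4.49 ± 1.07, and the number expected at 364426 counts was 338 ± 85.3, 422 ± 87.6, 299 ± 100, 217 ± 29.5, 373 ± 73.4 and 308 ± 39.2. None of these passed after adjustment, at 0.5 or more. The smallest exact p that a design allows was 0.1 or 0.333 throughout, so no composition test could have passed the threshold. The permutation tests did not use the pairing of exomere libraries by number. From pool 1 to pool 2 the top-10 share rose in every pair (97.9% to 99.1%, 85.6% to 90.7% and 83.9% to 84.1%). Rarefied richness fell in every pair (240 to 185, 389 to 337 and 386 to 374). The miR-1246 share and the effective number moved in both directions, and no paired test was run. In the edgeR test the log2 change of miR-1246 passed the threshold in none of the 8 comparisons. It was largest in size for pool 3 minus pool 2 media, at -3.92 (SE 1.80, adjusted p 0.111).

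**Figure D1:**
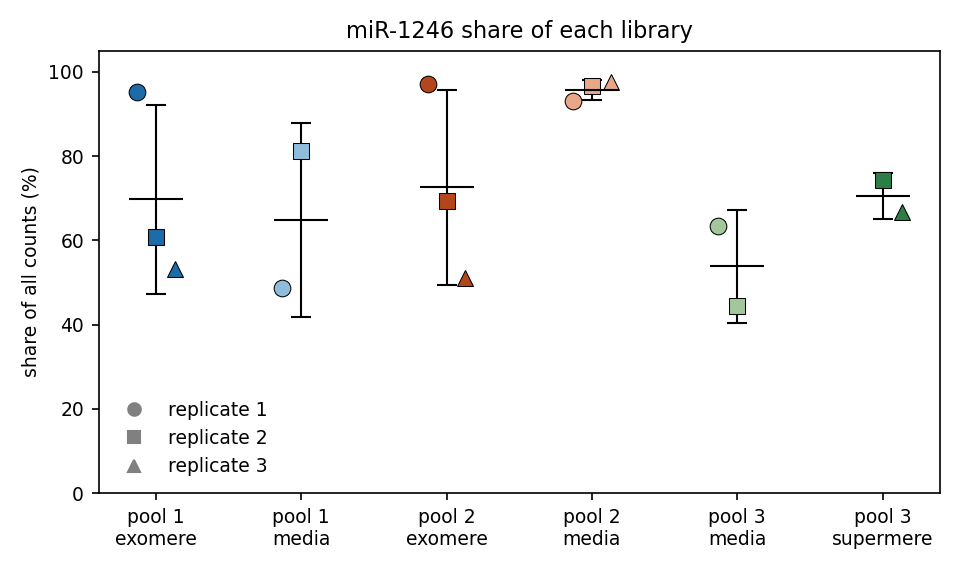
Share of the total count taken by miR-1246, in percent, for each group. Points are libraries with a shape for the replicate number, bars are group means and whiskers are SD; the 3 pool 2 media libraries lie between 93.1% and 97.5%.

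Outside miR-1246, a library held 151643 to 1296105 counts. By the mean over all groups the next most abundant was miR-92a-3p. Its sequence lies in MIR92A1 of the miR-17~92 cluster, an oncogenic cluster driven by MYC, and also in MIR92A2 on chromosome X. Its counts therefore cannot be assigned to the miR-17~92 cluster alone. miR-92a-3p had 9392 ± 6165 normalised CPM in pool 1 media and 25447 ± 3568 in pool 1 exomere. It reached 32871 ± 1846 in pool 2 exomere, 29114 ± 17580 in pool 2 media, 32253 ± 10280 in pool 3 media and 15644 ± 3749 in pool 3 supermere. miR-21-5p was above it in pool 1 media, and miR-10a-5p, miR-320a-3p, miR-335-5p, miR-423-5p and miR-320b were above it in pool 3 supermere. miR-21-5p, which is raised in many tumours, ranged from 2823 ± 987 in pool 3 media to 18892 ± 9005 in pool 1 media. miR-320a-3p, which is made without Drosha, ranged from 3350 ± 567 in pool 1 media to 29284 ± 6465 in pool 3 supermere. The other 6 of the 10 most abundant were miR-10a-5p, miR-335-5p, miR-24-3p, miR-22-3p, miR-423-5p and miR-29a-3p. Their lowest group means were 5236, 1871, 2467, 895, 1339 and 2643 normalised CPM, and their highest were 34139, 23793, 27280, 16130, 22431 and 14866. Averaged over the 6 groups, markers of blood cells and endothelium were low, at 39.6 CPM for miR-142-5p and 9.22 for miR-142-3p. So were markers of other tissues, at 49.8 for miR-1-3p and 13.9 for miR-499a-5p. Levels differed between groups behind these averages. From pool 1 to pool 3 media the log2 changes of the 4 were, in that order, -4.29, -6.08, 2.15 and -2.71.

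On principal components of log2 CPM, the first component (53.3% of the variance) ran from the pool 1 media libraries at -26.1 and -28.0 to the pool 3 libraries at 14.6 to 24.3. The pool 3 supermere libraries, at 19.0 and 24.3, lay among and beyond the pool 3 media libraries at 14.6 and 21.2. The pool 1 exomere libraries, at -12.1 to -3.98, overlapped the pool 2 media libraries at -10.8 to -3.12. The pool 2 exomere libraries lay at 4.14 to 8.31.

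**Figure D2:**
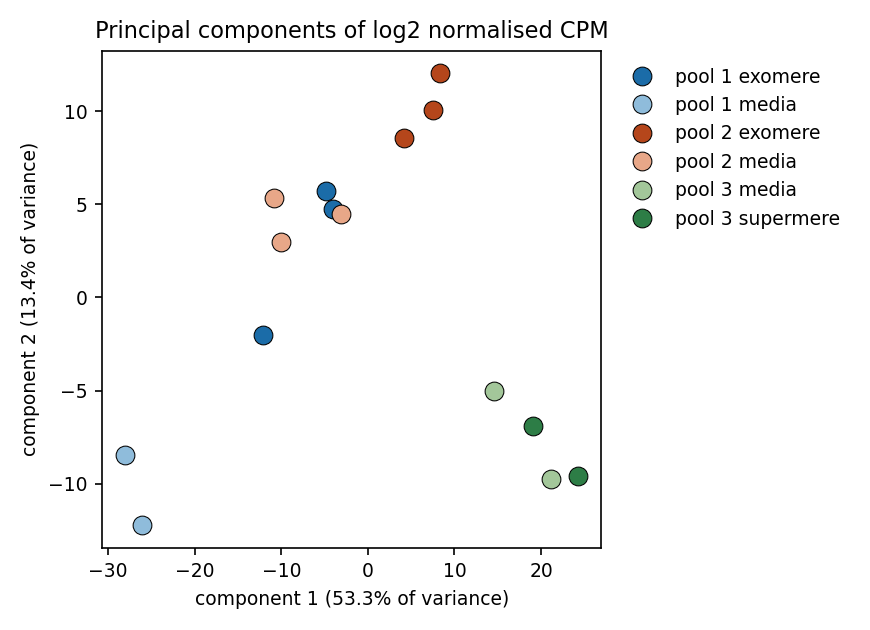
First and second principal components of the 15 libraries (53.3% and 13.4% of the variance), from log2 normalised CPM. Points are libraries coloured by group; pool 1 media lies at one end of the first component and all pool 3 libraries lie at the other.

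Fold changes are relative to TMM scaling, which follows the bulk of the miRNAs. Because the share of miR-1246 differed between libraries, scaling to the total count alone moved the median of all tested miRNAs by 2.18 on the log2 scale in pool 2 exomere minus media, by -3.30 in pool 2 minus pool 1 media and by 3.09 in pool 3 minus pool 2 media. In the other 5 comparisons that shift was -0.73 (pool 1 exomere minus media), -0.79 (supermere minus media), -0.51 (pool 2 minus pool 1 exomere), -0.32 (pool 3 minus pool 1 media) and 0.05 (supermere minus exomere). Of the 139 named changes, 22 reversed and 73 lost their call under total-count scaling. No list kept its call when camera estimated the inter-gene correlation: 34 of 80 list tests passed with the preset correlation and 0 with the estimated one.

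Exomere libraries of pool 1 were compared with media libraries of the same pool, to ask how the miRNAs of that preparation differ from those named media. miR-193a-5p rose 32.0-fold, from 11 ± 7.2 normalised CPM in media (n = 2) to 360 ± 112 in exomere (n = 3), a log2 change of 5.0 (SE 0.64, edgeR adjusted p 9.76e-07). miR-22-3p rose 9.75-fold, from 895 ± 263 to 8721 ± 3207 (log2 3.28, SE 0.50, adjusted p 4.62e-06), and miR-24-3p rose 5.14-fold, from 2467 ± 749 to 12685 ± 3613. miR-29b-3p and miR-29c-3p, of a family that targets collagen mRNAs, rose by log2 3.46 (SE 0.52) and 2.95 (SE 0.51). The other named rises were miR-130b-3p (log2 2.72), miR-320b (2.33), miR-320d (2.24), miR-320c (2.20) and miR-423-3p (2.18). let-7a-5p, of the family that represses RAS mRNAs, was 7.44-fold lower in exomere, at 360 ± 293 against 2682 ± 1143 (log2 -2.90, SE 0.49, adjusted p 3.95e-05). let-7f-5p (log2 -2.88), miR-186-5p (-2.55), let-7d-5p (-2.48), miR-15b-5p (-2.43), let-7c-5p (-2.31), miR-374a-5p (-2.20), miR-429 (-2.09) and let-7g-5p (-2.07) also fell. miR-7704 had the largest fall of those named (log2 -7.04, SE 1.61, adjusted p 0.00832), from a level that differed between the media libraries (279 ± 321), and its log2 change was -4.60 without pool 1 media replicate 2, -7.90 without media replicate 1 and -6.39 without exomere replicate 2. Without exomere replicate 1 it had 1 count left in exomere, a fall of at least 151-fold by its 95% counting interval. Without media replicate 2 the pooled ratio was 26.95 (14.3 to 57.2), and these intervals leave out the spread between libraries. Without media replicate 1 the rise of miR-193a-5p was 61.1-fold, and without media replicate 2 those of miR-29b-3p and miR-29c-3p were log2 4.13 and 3.73. Without exomere replicate 1 let-7a-5p was 13.8-fold lower, and the log2 changes of let-7f-5p, let-7d-5p, let-7c-5p and miR-374a-5p were -3.75, -3.22, -3.05 and -2.93.

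In this comparison 92 of 306 miRNAs passed, 44 higher and 48 lower, and 128 had an unadjusted p under 0.05. let-7 members fell in 8 of 9 cases (8 adjusted over the list alone; median log2 -2.31, adjusted p 0.000365, and 0.329 with an estimated correlation). miR-320 members rose in 3 of 5 (5 adjusted over the list alone; median 2.20, adjusted p 0.00476, 0.329 estimated). miR-200 members, which repress the mesenchymal factors ZEB1 and ZEB2, fell in 4 of 7 (4 adjusted over the list alone; median -1.76, adjusted p 0.0054, 0.329 estimated). The colorectal list fell in 7 of 14 (9 adjusted over the list alone; median -1.35, adjusted p 0.00476, 0.329 estimated). The miR-26 and miR-30 list fell in 3 of 7 (4 adjusted over the list alone; adjusted p 0.0385, 0.329 estimated), and lost its call without pool 1 exomere replicate 3 (0.0574) or pool 1 media replicate 1 (0.115). The other 5 lists did not pass (adjusted p 0.117 to 0.666); in the blood and endothelial list 1 of 4 fell (1 adjusted over the list alone; 0.117, 0.329 estimated), miR-142-3p (log2 -2.30, SE 0.75). Removing a GC trend, an alternative chosen after the data were seen, moved the colorectal median to -0.76.

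The count depended on single libraries: it was 55 without pool 1 exomere replicate 2, 60 without replicate 3 and 52 without pool 1 media replicate 1. let-7c-5p lost its call without pool 1 exomere replicate 2 or 3 or without either media library, with adjusted p up to 0.215. limma-voom called 153 miRNAs. Scaling to the total count called 5, all lower, and ended 17 of the 20 named calls. DESeq2 size factors gave 35 higher and 73 lower calls, and the total without the most abundant miRNA 35 and 64.

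The same question was asked of the exomere and media libraries of pool 2. miR-193a-5p rose 3.70-fold, from 240 ± 209 normalised CPM in media (n = 3) to 886 ± 231 in exomere (n = 3), a log2 change of 1.89 (SE 0.46, edgeR adjusted p 0.00429); without pool 2 media replicate 1 the rise was 7.44-fold. miR-29b-3p rose 3.38-fold (log2 1.76, SE 0.41) and miR-193b-3p 3.22-fold (log2 1.69, SE 0.40). miR-22-3p rose 2.75-fold, from 5866 ± 1736 to 16130 ± 4328 (log2 1.46, SE 0.40, adjusted p 0.00767). The other named rises were miR-671-5p (log2 1.62), miR-29c-3p (1.53), miR-423-3p (1.47), miR-452-5p (1.44), miR-1301-3p (1.28) and miR-29a-3p (1.24). let-7f-5p was 5.13-fold lower, at 76.2 ± 42.4 against 387 ± 89.2 (log2 -2.36, SE 0.47, adjusted p 0.000952), and let-7a-5p 4.41-fold lower (log2 -2.14, SE 0.46). miR-7-5p, which targets the EGFR mRNA, was 4.05-fold lower, at 504 ± 41.8 against 2040 ± 482 (log2 -2.02, SE 0.38, adjusted p 0.000752). miR-200c-3p (log2 -2.05), miR-16-5p (-2.04), let-7g-5p (-2.03), miR-194-5p (-1.97), miR-15b-5p (-1.55), miR-200a-3p (-1.50) and miR-146a-5p (-1.49) also fell. Scaled to the total count alone, 7 of these 20 changed sign: miR-200c-3p (0.03), miR-16-5p (0.34), miR-7-5p (0.35), miR-194-5p (0.30), miR-15b-5p (0.74), miR-200a-3p (0.69) and miR-146a-5p (0.51), against a median shift of 2.18.

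In pool 2, 70 of 306 miRNAs passed, 31 higher and 39 lower, and 92 had an unadjusted p under 0.05. let-7 members fell in 6 of 9 cases (8 adjusted over the list alone; median log2 -1.90, adjusted p 0.000389, 0.377 with an estimated correlation), with a median of 0.36 when scaled to the total count alone and of -0.96 after the GC trend was removed. miR-200 members fell in 5 of 7 (6 adjusted over the list alone; median -1.43, adjusted p 0.00217, 0.377 estimated), with a median of 0.73 when scaled to the total count and of -0.75 after GC removal. The colorectal list fell in 5 of 14 (5 adjusted over the list alone; median -0.89, adjusted p 0.00791, 0.551 estimated), with a median of 1.59 when scaled to the total count and of -0.34 after GC removal. miR-320 members rose in 2 of 5 (3 adjusted over the list alone; median 0.90, adjusted p 0.0431, 0.551 estimated). The miR-320 call was lost without exomere replicate 1 (0.0622) or 3 (0.0966) and without media replicate 2 (0.202) or 3 (0.0601). The other 6 lists did not pass (adjusted p 0.281 to 0.964).

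The count for pool 2 was 24 without exomere replicate 2, 26 without exomere replicate 3, 30 without media replicate 2 and 32 without media replicate 3. Leaving out exomere replicate 2 ended the calls of miR-671-5p, miR-29c-3p, miR-22-3p, miR-452-5p, miR-1301-3p and miR-29a-3p. Without exomere replicate 3 the calls of miR-29c-3p, miR-452-5p, miR-1301-3p, miR-29a-3p, miR-15b-5p and miR-146a-5p ended. Without media replicate 2 those of miR-423-3p, miR-452-5p, miR-1301-3p and miR-15b-5p ended, and without media replicate 3 those of miR-22-3p, miR-452-5p, miR-1301-3p and miR-29a-3p. Their highest adjusted p-values were 0.0557 for miR-671-5p, 0.0587 for miR-29c-3p, 0.0683 for miR-423-3p, 0.0599 for miR-22-3p, 0.0961 for miR-452-5p, 0.117 for miR-1301-3p, 0.110 for miR-29a-3p, 0.0675 for miR-15b-5p and 0.0746 for miR-146a-5p. limma-voom called 124 miRNAs. Scaling to the total count called 56, all higher, and ended 3 named calls beside the 7 that changed sign. The total without the most abundant miRNA gave 13 higher and 48 lower calls and ended those of miR-29c-3p (0.0553), miR-452-5p (0.0924), miR-1301-3p (0.0878) and miR-29a-3p (0.0924). Without a low-count filter those of miR-671-5p (0.0511), miR-452-5p (0.152), miR-1301-3p (0.202) and miR-29a-3p (0.127) ended.

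Across miRNAs, which are not independent replicates, the exomere-minus-media changes of pools 1 and 2 correlated with a Pearson r of 0.69 and a Spearman rho of 0.71, in comparisons that share no library. miR-193a-5p, miR-22-3p and let-7a-5p were among 54 miRNAs called in both, 26 higher in both, 28 lower in both and 0 in opposite directions. Independent lists of those sizes would share 4.46 higher and 6.12 lower. In the test of the difference between the pools, miR-193a-5p was the only miRNA past the threshold, with a smaller rise in pool 2 by log2 -3.11 (SE 0.72, adjusted p 0.0346), and 30 miRNAs had an unadjusted p under 0.05. The call of miR-193a-5p ended without pool 1 exomere replicate 2, pool 1 media replicate 2, pool 2 exomere replicate 3 or pool 2 media replicate 1, with adjusted p up to 0.269; its value was -2.10 without pool 2 media replicate 1 and -4.04 without pool 1 media replicate 1. DESeq2 called 5 miRNAs and limma-voom 8. DESeq2 size factors in edgeR called 2 and scaling to the total count 1, without miR-193a-5p, while 0 passed with the additive replicate block, with the stricter filter, with only the groups compared or with the total without the most abundant miRNA. The count was 5 without pool 1 exomere replicate 1, 3 without pool 2 exomere replicate 1 and 2 without both, an omission chosen after the data were seen.

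**Figure D3:**
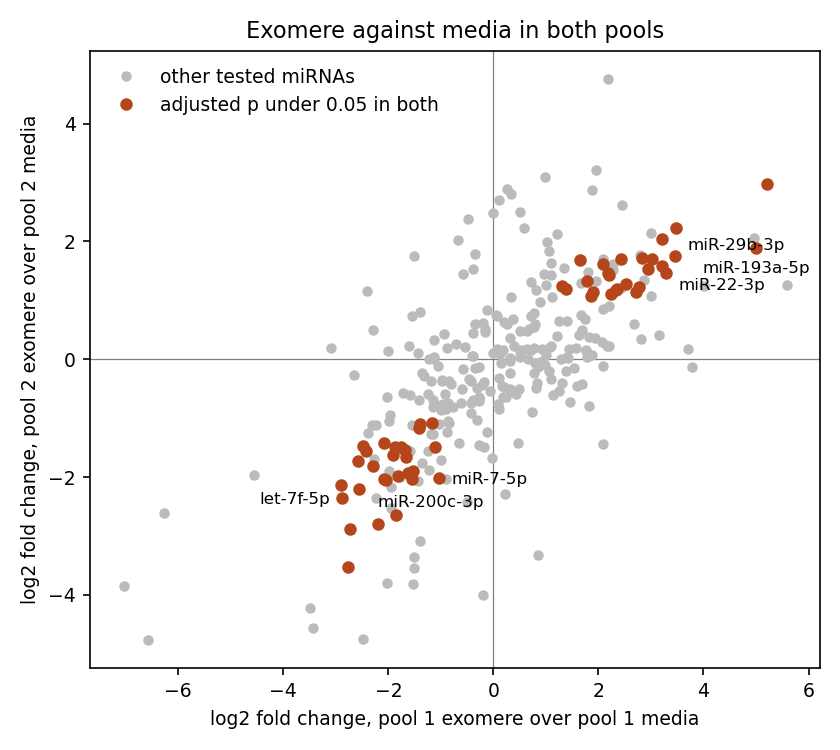
Log2 fold change of 306 miRNAs, exomere minus media, in pool 1 (horizontal) and pool 2 (vertical), TMM scaling. Points are miRNAs and the coloured ones are the 54 past the threshold in both pools, all in the same direction; scaled to the total count alone, let-7 and miR-200 medians in pool 2 change sign.

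Supermere libraries of pool 3 were compared with pool 3 media, the only comparison of supermeres within a pool. The 2 supermere libraries, with 1296105 and 151643 counts outside miR-1246, had a Spearman correlation of 0.870 with each other. With pool 3 media libraries the mean was 0.866 (0.839 to 0.891), so the supermere replicates were about as close to media as to each other. let-7g-5p was 8.50-fold lower in supermere, at 274 ± 112 normalised CPM (n = 2) against 2320 ± 479 (n = 2), a log2 change of -3.09 (SE 0.51, edgeR adjusted p 8.67e-05). miR-378a-3p was 8.24-fold lower, at 43.5 ± 1.66 against 356 ± 291 (log2 -3.04, SE 0.53, adjusted p 0.000109), and 12.9-fold lower without pool 3 media replicate 1 but 3.47-fold without media replicate 2. let-7f-5p was 7.70-fold lower, at 84.6 ± 23.6 against 647 ± 63.2, and let-7a-5p 5.54-fold lower, at 121 ± 9.78 against 669 ± 110 (log2 -2.47, SE 0.56, adjusted p 0.0027). miR-28-3p (log2 -2.63), miR-25-3p (-2.26), miR-425-5p (-2.08) and miR-484 (-1.83) also fell. No miRNA above 100 CPM rose past the threshold. miR-425-5p and miR-484 lost their calls without pool 3 supermere replicate 3 (adjusted p 0.0571 and 0.0889), and miR-484 also when only the groups compared entered the fit (0.0975).

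Between supermere and media 20 of 306 miRNAs passed, 7 higher and 13 lower, and 60 had an unadjusted p under 0.05. None of the 10 lists passed (adjusted p 0.246 to 0.873). let-7 members fell in 3 of 9 cases (3 adjusted over the list alone), with a median of -1.07 (adjusted p 0.246, 0.754 with an estimated correlation; median -2.03 when scaled to the total count), and the list passed without pool 3 media replicate 2 (0.0326). The list of other tissues passed without pool 3 supermere replicate 2 (0.0149). The count was 11 without pool 3 media replicate 2, 13 with limma-voom and 0 when scaled to the total count. DESeq2 size factors gave 10 higher and 12 lower calls.

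Exomere libraries of pools 1 and 2 were compared with each other, to ask how far preparations of the same name differ between pools. miR-200c-3p was 10.2-fold lower in pool 2, at 73.3 ± 32.2 normalised CPM (n = 3) against 746 ± 585 (n = 3), a log2 change of -3.36 (SE 0.48, edgeR adjusted p 4.38e-06). miR-200b-3p was 6.61-fold lower, at 175 ± 53.5 against 1157 ± 927 (log2 -2.72, SE 0.44, adjusted p 1.60e-05). miR-194-5p, enriched in gut epithelium, was 4.31-fold lower, at 308 ± 74.9 against 1329 ± 845 (log2 -2.11, SE 0.42, adjusted p 0.000399). let-7f-5p (log2 -2.30), let-7a-5p (-2.01), miR-429 (-1.72) and let-7g-5p (-1.17) also fell. miR-193b-3p rose 2.99-fold, from 251 ± 66.7 to 749 ± 143 (log2 1.58, SE 0.40, adjusted p 0.00565), and miR-671-5p (log2 1.53) and miR-1301-3p (1.49) rose. Several falls were smaller without pool 1 exomere replicate 1: miR-200c-3p was then 5.67-fold, miR-200b-3p 3.57-fold and miR-194-5p 2.76-fold lower, and the log2 change of let-7f-5p was -1.42.

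Between exomere groups 28 of 306 miRNAs passed, 6 higher and 22 lower, and 69 had an unadjusted p under 0.05. With the replicate number as a block nested in the preparation, 44 passed, 15 higher and 29 lower. let-7 members fell in 5 of 9 cases (7 adjusted over the list alone; median log2 -1.65, adjusted p 0.00132, 0.286 with an estimated correlation), with a median of -0.85 after the GC trend was removed. miR-200 members fell in 3 of 7 (3 adjusted over the list alone; median -0.53, adjusted p 0.0214, 0.406 estimated), and the call ended without pool 1 exomere replicate 1 (0.0709) or pool 2 exomere replicate 3 (0.0619). The colorectal list fell in 4 of 14 (5 adjusted over the list alone; median -0.53, adjusted p 0.0126, 0.406 estimated), with a median of -0.03 after GC removal, and its call ended without pool 1 exomere replicate 1 (0.0932). The miR-26 and miR-30 list fell in 2 of 7 (2 adjusted over the list alone; adjusted p 0.0126, 0.286 estimated). The other 6 lists did not pass (adjusted p 0.0890 to 0.955), of which the blood and endothelial list passed without pool 1 exomere replicate 2 (0.0141).

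The count between exomere groups was 16 without pool 1 exomere replicate 1, 15 without pool 2 exomere replicate 2 and 14 without both libraries numbered 1. Without pool 1 exomere replicate 1 the calls of miR-671-5p, let-7a-5p and let-7g-5p ended, with log2 changes of -1.12 for let-7a-5p and -0.72 for let-7g-5p. Without pool 2 exomere replicate 2 those of miR-193b-3p, miR-671-5p, miR-1301-3p and let-7g-5p ended, and without replicate 3 those of miR-671-5p, miR-1301-3p and let-7g-5p. The highest adjusted p-values were 0.142 for miR-193b-3p, 0.166 for miR-671-5p, 0.151 for miR-1301-3p, 0.0985 for let-7a-5p and 0.318 for let-7g-5p. limma-voom called 63 miRNAs. Scaling to the total count called 5, all lower and 4 of them among the 28, and ended all 10 named calls. The total without the most abundant miRNA gave 3 higher and 26 lower calls and ended those of miR-671-5p (0.0593) and miR-1301-3p (0.0520). Without a low-count filter those of miR-193b-3p (0.0800), miR-671-5p (0.165) and miR-1301-3p (0.149) ended, and without both libraries numbered 1 those of miR-193b-3p (0.109), miR-671-5p (0.0698) and let-7g-5p (0.0955). The call of let-7g-5p also ended with DESeq2 size factors (0.0666) and the stricter filter (0.0679).

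Media libraries of pool 2 were compared with those of pool 1, which share a preparation name and differ in pool. miR-193a-5p rose 21.2-fold, from 11 ± 7.2 normalised CPM (n = 2) to 240 ± 209 (n = 3), a log2 change of 4.41 (SE 0.63, edgeR adjusted p 3.88e-06), and 40.6-fold without pool 1 media replicate 1 but 10.6-fold without pool 2 media replicate 1. The other named rises were miR-1290 (log2 3.36, SE 1.06), miR-29b-3p (2.86), miR-22-3p (2.71), miR-29c-3p (2.57), miR-107 (2.53), miR-24-3p (2.27), miR-130b-3p (2.25), miR-423-5p (1.76) and miR-320c (1.74). miR-30c-5p was 19.3-fold lower, at 20.6 ± 11.7 against 402 ± 226 (log2 -4.27, SE 0.81, adjusted p 0.000554), and 11.6-fold lower without pool 1 media replicate 1. miR-200c-3p was 10.2-fold lower, at 302 ± 58.3 against 3074 ± 1153, and miR-200b-3p 8.72-fold lower, at 489 ± 112 against 4260 ± 967 (log2 -3.12, SE 0.46, adjusted p 3.88e-06). miR-30b-5p (log2 -3.59), miR-374a-5p (-3.43), miR-186-5p (-3.32), let-7f-5p (-2.82), let-7a-5p (-2.77), let-7d-5p (-2.66) and let-7c-5p (-2.62) also fell. Scaled to the total count alone, 8 of the 10 rises changed sign: miR-29b-3p (-0.25), miR-22-3p (-0.47), miR-29c-3p (-0.51), miR-107 (-0.88), miR-24-3p (-0.93), miR-130b-3p (-1.18), miR-423-5p (-1.59) and miR-320c (-1.71), against a median shift of -3.30.

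Of 306 miRNAs 75 passed, 32 higher and 43 lower in pool 2 media, and 112 had an unadjusted p under 0.05. let-7 members fell in 7 of 9 cases (7 adjusted over the list alone; median log2 -2.66, adjusted p 0.00136, 0.192 with an estimated correlation). The miR-26 and miR-30 list fell in 5 of 7 (5 adjusted over the list alone; median -2.12, adjusted p 0.00391, 0.192 estimated). The colorectal list fell in 6 of 14 (6 adjusted over the list alone; median -0.90, adjusted p 0.00834, 0.382 estimated; median -0.20 after GC removal), and the blood and endothelial list in 2 of 4 (2 adjusted over the list alone; adjusted p 0.00834, 0.192 estimated). miR-200 members fell in 3 of 7 (3 adjusted over the list alone; adjusted p 0.0401, 0.382 estimated), and the call ended without pool 1 media replicate 2 (0.0548). miR-320 members rose in 3 of 5 (4 adjusted over the list alone; median 1.56, adjusted p 0.0361, 0.382 estimated), with a median of -1.89 when scaled to the total count, and the call ended without pool 1 media replicate 2 (0.131) or pool 2 media replicate 1 (0.0838). The other 4 lists did not pass (adjusted p 0.0689 to 0.905), of which the miR-17~92 list passed with the additive replicate block (0.0445), without pool 1 media replicate 1 (0.0386) or without pool 2 media replicate 3 (0.0420).

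miR-1290 lost its call without either pool 1 media library or without pool 2 media replicate 2 or 3 (adjusted p up to 0.228), with the additive replicate block (0.0659) and with the total without the most abundant miRNA (0.0620), and let-7c-5p without pool 1 media replicate 1 or any pool 2 media library (up to 0.167). miR-423-5p and miR-320c lost theirs without pool 1 media replicate 2 (0.0588 and 0.0802). Without that library the log2 changes of miR-1290, miR-29b-3p and miR-29c-3p were 4.12, 3.53 and 3.35, and without pool 2 media replicate 1 that of miR-423-5p was 1.18. Scaling to the total count called 170 miRNAs, all lower, and ended 2 named calls beside the 8 that changed sign. DESeq2 size factors gave 25 higher and 52 lower calls. The changes between pools in exomere and in media correlated across miRNAs with a Pearson r of 0.71 and a Spearman rho of 0.69. miR-200c-3p and let-7a-5p were among 23 miRNAs called in both, 4 higher and 19 lower, against 0.627 and 3.09 for independent lists.

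Pool 3 media was compared with pool 2 media, again groups of the same name from different pools. miR-335-5p rose 5.07-fold, from 4141 ± 2143 normalised CPM (n = 3) to 21015 ± 1400 (n = 2), a log2 change of 2.34 (SE 0.43, edgeR adjusted p 3.69e-05). miR-320a-3p rose 4.32-fold, from 6522 ± 3350 to 28145 ± 1592 (log2 2.11, SE 0.42, adjusted p 0.000116). miR-484, also made without Drosha, rose 9.01-fold, from 288 ± 53.0 to 2593 ± 446 (log2 3.17, SE 0.42, adjusted p 1.18e-07). miR-99b-5p (log2 3.27), miR-3679-5p (2.89), miR-320b (2.18), miR-320c (2.1), miR-320d (2.04), miR-18a-3p (1.92) and miR-423-3p (1.71) also rose. miR-16-5p was 28.9-fold lower, at 36.3 ± 1.34 against 1053 ± 390 (log2 -4.85, SE 0.55, adjusted p 6.02e-09), and miR-200a-3p 12.6-fold lower, at 187 ± 29.4 against 2368 ± 685 (log2 -3.66, SE 0.48). miR-7-5p (log2 -3.34), miR-194-5p (-3.09), miR-15b-5p (-3.07), miR-429 (-2.82), miR-146a-5p (-2.77), miR-30e-5p (-2.70), miR-200b-5p (-2.65) and miR-148a-3p (-2.59) also fell. Without pool 3 media replicate 2 the log2 changes of miR-15b-5p, miR-429 and miR-148a-3p were -3.77, -3.42 and -3.96, and without replicate 1 that of miR-148a-3p was -1.91. Scaled to the total count alone, 7 of the 10 falls changed sign: miR-194-5p (0.13), miR-15b-5p (0.25), miR-429 (0.42), miR-146a-5p (0.37), miR-30e-5p (0.47), miR-200b-5p (0.39) and miR-148a-3p (0.81), against a median shift of 3.09.

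Here 123 of 306 miRNAs passed, 50 higher and 73 lower in pool 3 media, and 147 had an unadjusted p under 0.05. miR-320 members rose in 5 of 5 cases (5 adjusted over the list alone; median log2 2.11, adjusted p 0.0013, 0.291 with an estimated correlation). miR-200 members fell in 7 of 7 (7 adjusted over the list alone; median -2.50, adjusted p 0.0013, 0.291 estimated), with a median of 0.47 when scaled to the total count and of -1.07 after the GC trend was removed. The colorectal list fell in 9 of 14 (9 adjusted over the list alone; adjusted p 0.00688, 0.378 estimated), the miR-17~92 list in 7 of 10 (7 adjusted over the list alone; adjusted p 0.0158, 0.291 estimated) and the miR-26 and miR-30 list in 4 of 7 (4 adjusted over the list alone; adjusted p 0.0437, 0.291 estimated). The medians of these 3 lists were -1.87, -2.01 and -1.57, and became 1.35, 1.24 and 1.60 when scaled to the total count and -0.80, -1.16 and -0.84 after GC removal. The miR-26 and miR-30 call ended without pool 2 media replicate 2 (0.0547) or pool 3 media replicate 1 (0.0877). The other 5 lists did not pass (adjusted p 0.597 to 0.807), among them let-7, of which 3 of 9 members fell (3 adjusted over the list alone; median 0.15, mean -1.06), with a median of 1.60 after GC removal and of 3.23 when scaled to the total count. In the blood and endothelial list 1 of 4 fell (1 adjusted over the list alone; 0.597, 0.832 estimated), miR-142-5p (log2 -3.16, SE 0.69). The count was 79 without pool 3 media replicate 1, and scaling to the total count called 130 miRNAs, all higher, and ended 3 named calls beside the 7 that changed sign.

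Pool 3 media against pool 1 media held the most calls of the 8 comparisons with TMM scaling; scaled to the total count alone it held 41, against 170 for pool 2 minus pool 1 media and 130 for pool 3 minus pool 2 media. miR-193a-5p rose 51.4-fold, from 11 ± 7.2 normalised CPM (n = 2) to 579 ± 93.1 (n = 2), a log2 change of 5.68 (SE 0.68, edgeR adjusted p 2.35e-08), and 98.2-fold without pool 1 media replicate 1. miR-320c rose 14.3-fold, from 526 ± 175 to 7545 ± 2495 (log2 3.84, SE 0.52, adjusted p 6.46e-08), and miR-335-5p 11.2-fold, from 1871 ± 840 to 21015 ± 1400. miR-3679-5p (log2 4.21), miR-130b-3p (3.88), miR-1301-3p (3.87), miR-484 (3.74), miR-320b (3.73), miR-320d (3.60) and miR-29b-3p (3.51) also rose. miR-200b-3p was 48.8-fold lower, at 87.2 ± 2.81 against 4260 ± 967 (log2 -5.61, SE 0.61, adjusted p 2.49e-09), and miR-194-5p 33.1-fold lower, at 141 ± 26.6 against 4695 ± 301.5. miR-30c-5p had 2 counts in pool 3 media, both in replicate 2, and 2349 in pool 1 media, a normalised ratio of 718 (95% counting interval 198 to 5932). Without pool 1 media replicate 1 it was 395 (109 to 3275), and without pool 3 media replicate 2, which leaves 0 counts, at least 114. miR-7704 (log2 -7.33), miR-374a-5p (-6.17), miR-186-5p (-5.31), miR-429 (-5.21), miR-30b-5p (-5.16), miR-200c-3p (-4.99) and miR-16-5p (-4.75) also fell. The call of miR-7704 ended without a low-count filter (0.0519), and its log2 change was -4.87 without pool 1 media replicate 2 and -8.19 without replicate 1. Without pool 3 media replicate 1 or 2 it had 2 or 3 counts left there, falls of at least 72.1-fold and 24.7-fold by their 95% counting intervals. Without pool 1 media replicate 2 the pooled ratio of miR-7704 was 33.75 (14.18 to 105.3). Without pool 3 media replicate 2 the log2 changes of miR-186-5p and miR-429 were -6.44 and -5.81, and without replicate 1 that of miR-130b-3p was 3.27. Without pool 1 media replicate 1 that of miR-1301-3p was 4.51, and without replicate 2 those of miR-29b-3p and miR-16-5p were 4.18 and -4.10.

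Between these media groups 182 of 306 miRNAs passed, 81 higher and 101 lower in pool 3, and 192 had an unadjusted p under 0.05. miR-200 members fell in 7 of 7 cases (7 adjusted over the list alone; median log2 -4.18, adjusted p 0.00158, 0.224 with an estimated correlation), with a median of -2.62 after the GC trend was removed. miR-320 members rose in 5 of 5 (5 adjusted over the list alone; median 3.60, adjusted p 0.00158, 0.224 estimated). In the colorectal list 11 of 14 fell and 1 rose (the same numbers adjusted over the list alone; adjusted p 0.00158, 0.224 estimated). The miR-26 and miR-30 list fell in 6 of 7 (6 adjusted over the list alone; adjusted p 0.00426, 0.224 estimated), and the miR-17~92 list fell in 7 of 10 with 1 rise (7 and 1 adjusted over the list alone; adjusted p 0.0153, 0.224 estimated). let-7 members fell in 8 of 9 (8 adjusted over the list alone; median -2.19, adjusted p 0.0153, 0.248 estimated), with a median of -0.36 after GC removal. The blood and endothelial list fell in 3 of 4 (4 adjusted over the list alone; adjusted p 0.0341, 0.224 estimated). The let-7 and blood calls ended without pool 3 media replicate 2 (0.0636 and 0.0600). After GC removal the medians of the colorectal, miR-26 and miR-30, miR-17~92 and blood lists moved from -2.87, -3.33, -3.71 and -5.91 to -0.78, -1.17, -1.49 and -3.56. The other 3 lists did not pass (adjusted p 0.393 to 0.946). Scaling to the total count called 41 miRNAs, 7 higher and 34 lower, and ended 9 of the 20 named calls. The total without the most abundant miRNA gave 61 higher and 127 lower calls.

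**Figure D4:**
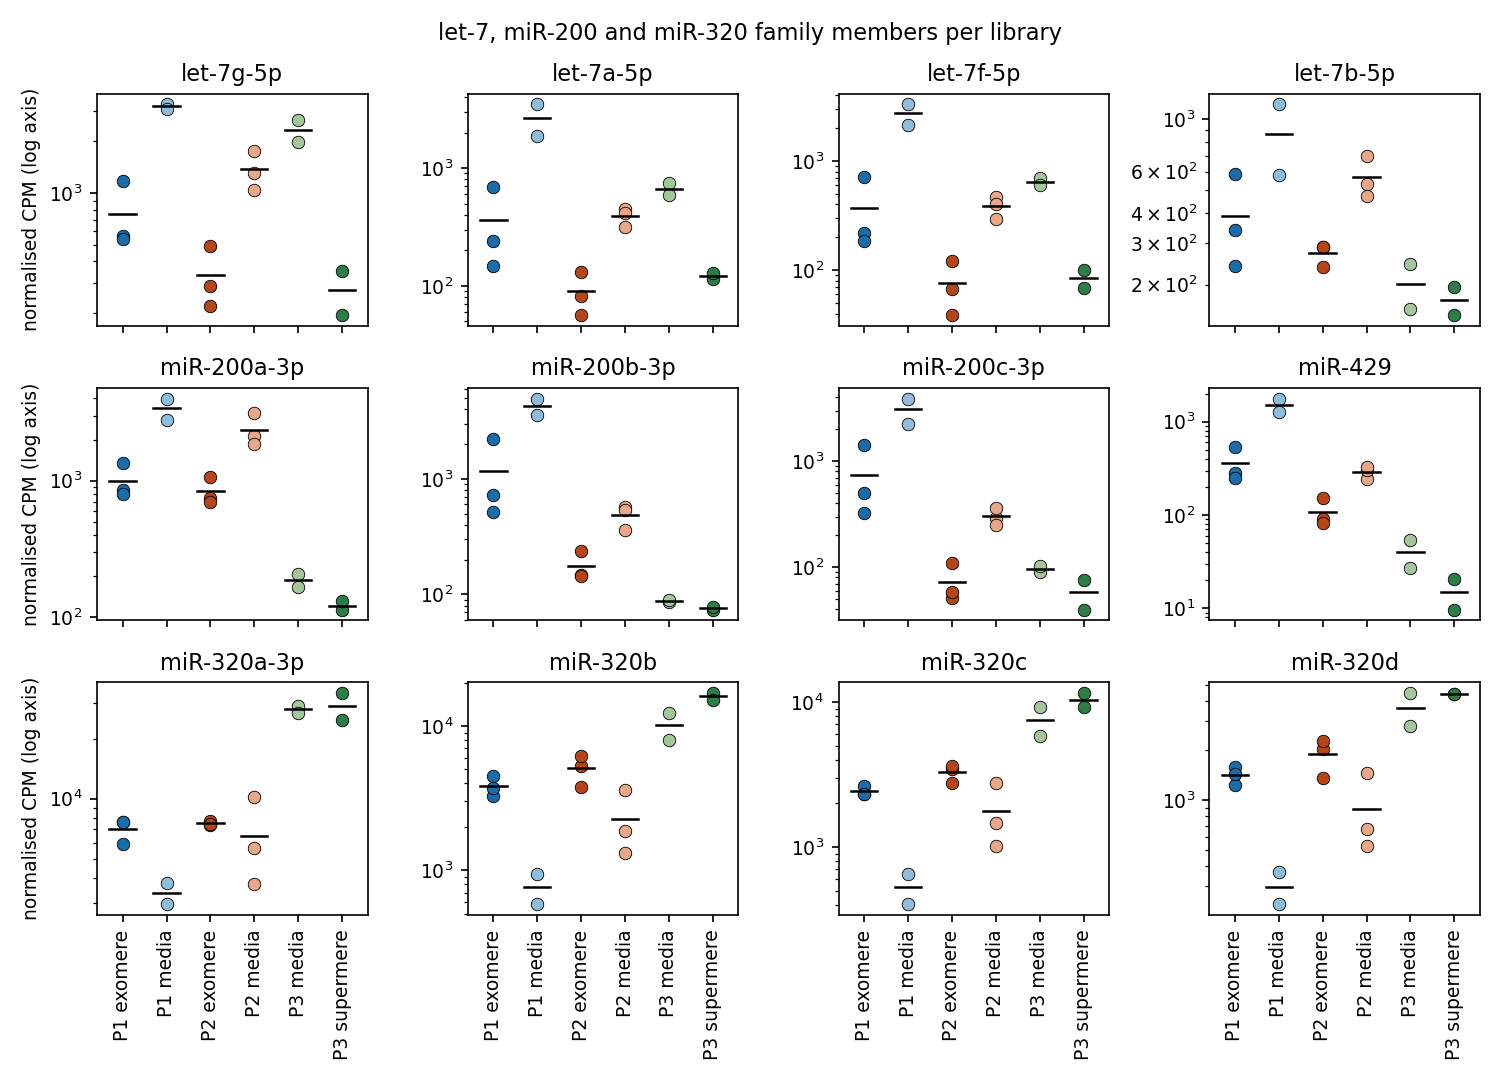
Normalised CPM (log axis) of the 4 most abundant members of the let-7, miR-200 and miR-320 families in each group. Points are libraries and lines are group means, on TMM scaling; in pool 3 minus pool 2 media all miR-320 members rose and all miR-200 members fell, and the miR-200 median changes sign when scaled to the total count alone.

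Pool 3 supermere was compared with pool 2 exomere, the carriers named by the study, which differ in pool as well. miR-24-3p was 7.62-fold lower in supermere, at 3580 ± 1172 normalised CPM (n = 2) against 27280 ± 6325 (n = 3), a log2 change of -2.93 (SE 0.48, edgeR adjusted p 1.49e-05). miR-148a-3p was 10.8-fold lower, at 379 ± 100 against 4087 ± 1698 (log2 -3.43, SE 0.63, adjusted p 0.000167), and miR-20a-5p 24.7-fold lower, at 6.41 ± 7.37 against 195 ± 71.1 (log2 -4.63, SE 0.64, adjusted p 2.19e-06). Without pool 3 supermere replicate 2, which leaves 1 count in supermere, miR-20a-5p was at least 30.8-fold lower by its 95% counting interval. Without replicate 3 its pooled ratio was 17.9 (13.7 to 23.8), and these intervals leave out the spread between libraries. miR-15b-5p (log2 -3.10), miR-16-5p (-2.87), miR-148b-3p (-2.83), miR-200a-3p (-2.79), miR-93-5p (-2.51), miR-378a-3p (-2.50) and miR-222-3p (-2.50) also fell. miR-320a-3p rose 3.89-fold, from 7533 ± 198 to 29284 ± 6465 (log2 1.96, SE 0.42, adjusted p 0.000365), and miR-335-5p 3.18-fold, from 7476 ± 1029 to 23793 ± 1702 (log2 1.67, SE 0.43). miR-339-5p (log2 3.96), miR-18a-3p (3.18), let-7d-3p (1.76), miR-320b (1.66), miR-320c (1.66), miR-3679-5p (1.62), miR-10a-5p (1.59) and miR-423-5p (1.54) also rose. The calls of miR-18a-3p, let-7d-3p, miR-10a-5p and miR-423-5p ended without pool 3 supermere replicate 2 (adjusted p 0.0877, 0.124, 0.762 and 0.108), the log2 changes of miR-339-5p, miR-18a-3p, let-7d-3p and miR-10a-5p were then 1.77, 1.32, 1.07 and 0.25, and the libraries of the 2 groups overlapped for miR-10a-5p. Those of miR-15b-5p and miR-148b-3p were then -4.36 and -3.60. Without replicate 3 the log2 changes of miR-339-5p, miR-18a-3p, miR-10a-5p and miR-16-5p were 4.78, 3.96, 2.27 and -3.45.

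Of 306 miRNAs 80 passed, 22 higher and 58 lower in supermere, and 117 had an unadjusted p under 0.05. The miR-17~92 list fell in 7 of 10 cases (9 adjusted over the list alone; median log2 -2.33, adjusted p 0.000586, 0.237 with an estimated correlation). miR-320 members rose in 4 of 5 (5 adjusted over the list alone; median 1.66, adjusted p 0.00136, 0.334 estimated). miR-200 members fell in 4 of 7 (6 adjusted over the list alone; median -1.74, adjusted p 0.00425, 0.334 estimated), and the call ended without pool 3 supermere replicate 2 (0.0710). The other 7 lists did not pass (adjusted p 0.0659 to 0.952), and 0 of 9 let-7 members were called (0 adjusted over the list alone). In the blood and endothelial list 2 of 4 fell (2 adjusted over the list alone; median -2.62, adjusted p 0.576, 0.813 estimated), miR-142-5p (log2 -2.85, SE 0.69) and miR-142-3p (-4.71, SE 1.70). The miR-10, miR-99/100 and miR-125 list, with 3 rises and 1 fall among 7 (3 and 1 adjusted over the list alone; 0.0659), passed without pool 2 exomere replicate 1 (0.0452) or pool 3 supermere replicate 3 (0.0330). Scaling to the total count called 0 miRNAs, and DESeq2 size factors gave 40 higher and 47 lower calls. The miR-17~92, miR-320 and miR-200 lists also passed in pool 3 minus pool 2 media, in the same directions. There 7 of 10, 5 of 5 and 7 of 7 members were called. Between supermere and media of pool 3 these lists did not pass, with 1 of 10, 0 of 5 and 1 of 7 members called. A difference between the carriers therefore cannot be told apart from one between the pools. The lists of miRNAs that share sequence with other RNAs and of other tissues passed in none of the 8 comparisons with all libraries. Of the former, miR-1290 rose in pool 2 minus pool 1 media (0 adjusted over the list alone), a call that also depended on single libraries. miR-1291 fell in both comparisons that involve supermere (1 adjusted over the list alone in each). Its log2 change was -6.42 (SE 2.03, edgeR adjusted p 0.0460) against pool 3 media and -6.09 (SE 2.00, 0.0191) against pool 2 exomere. These falls lie near the floor: its mean over the 6 groups was 3.51 CPM, and 3 counts equal 3.62 normalised CPM in supermere replicate 3 and 0.60 in replicate 2. In the list of other tissues, miR-499a-5p fell in pool 3 media against both other media groups (1 adjusted over the list alone in each).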

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

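Among the tests below, the U2 sequence search and the comparison of same-numbered exomere libraries were chosen after the results were seen, and so was the choice of the comparison pairs used for the GC and depth tests; what those 2 tests should show was written before their results were seen.

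The rise of miR-193a-5p from media to exomere differed between pools 1 and 2: its log2 change was 5.0 (SE 0.64) in pool 1 and 1.89 (SE 0.46) in pool 2, and the test of the difference gave -3.11 (SE 0.72, edgeR adjusted p 0.0346). It is listed here because the same contrast had a different size in the groups of the 2 pools. The level in pool 1 media was low, at 16.1 and 5.84 normalised CPM, against 107 to 481 in pool 2 media. From pool 1 to pool 2 the log2 change was 4.41 (SE 0.63) in media against 1.3 (SE 0.45) in exomere. The call did not hold with 4 of 11 libraries left out in turn (adjusted p up to 0.269), with the additive replicate block (0.0928), with DESeq2 size factors (0.0663), with the total without the most abundant miRNA (0.0832), with the stricter filter (0.0648) or with only the groups compared (0.0705). No technical or biological explanation was tested for it.

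Changes from media to exomere ordered the miRNAs like changes between media of different pools, in comparisons that share no library. For exomere minus media in pool 1 and pool 3 minus pool 2 media, Spearman's rho across miRNAs was 0.518. Removing a loess trend on GC content left 0.425 (bootstrap interval 0.324 to 0.52), above 0.259, which is 50% of the fitted value, and this argues against GC content as the whole cause. Thinning every library to 151643 counts outside miR-1246 left 0.602, which argues against unequal depth as the whole cause. That value is over 231 miRNAs and the 0.518 is over 306, so the depth and the set of miRNAs changed together. The bootstrap resamples miRNAs as if they were independent and does not measure the spread between libraries. No other explanation was tested. Among those that stay open is that the names exomere and media may cover preparations with overlapping content. The labels do not resolve whether such a difference is biological or procedural.

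miR-1246 took 44.4% to 97.5% of the counts of a library. Its mature sequence occurs unchanged in 7 annotated U2 genes, pseudogenes among them, as a mix-up of U2 fragments with miR-1246 requires. U2 fragments are therefore a candidate source of part of these counts. The test does not show how much. The same-numbered pairing of pool 1 and pool 2 exomere libraries had the smallest mean difference of the share, 4.2 points against 9.26 for the next, in 1 of 6 possible pairings. With 6 pairings, a shared step and coincidence cannot be told apart.

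Splitting the 6 pool 2 libraries into 3 and 3 in 10 ways, 1 split, the real one, called 70 miRNAs and the highest other called 0. For the 6 exomere libraries, 1 of 10 splits, the real one, called 28, the highest other called 1, and the splits that also part all 3 number pairs called 0. With 10 splits the share cannot fall under 0.05.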

How the results depend on the processing

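Added after the data were seen were the omission of both exomere libraries numbered 1, the GC trend removed from list medians, the list medians under DESeq2 size factors and without the most abundant miRNA, the total-count values relative to the median, and the thinning, with its test written before its result was seen; the rest were planned. Of the 139 named changes, DESeq2 and limma-voom kept the sign and the call of every one. Calls ended for 8 without a low-count filter, for 8 with the total without the most abundant miRNA, and for 2 each with DESeq2 size factors, the stricter filter, the additive block and only the groups compared. No named change reversed when 1 library was left out. Where that left a single library in a group, the lone library is assumed to vary like the others. Simulated 2-fold changes were recovered in 6.58% (supermere minus media) to 19.4% (pool 2 exomere minus media) of the changed miRNAs that passed the filter. The shares of depth, group size and spread in this were not separated. Thinning every library to 151643 counts outside miR-1246 left 231 miRNAs to test in place of 306. It gave 98 calls for exomere minus media in pool 1, 66 for that in pool 2 and 23 for supermere minus media, against 92, 70 and 20 at full depth. The cause of the changes listed here was not tested, except that total-count scaling moves with the share of miR-1246 by its construction.

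Scaled to the total count alone, 22 named changes reversed, 73 lost their call and 44 kept it. In pool 2 exomere minus media the reversed values were 0.030 (miR-200c-3p), 0.34 (miR-16-5p), 0.35 (miR-7-5p), 0.30 (miR-194-5p), 0.74 (miR-15b-5p), 0.69 (miR-200a-3p) and 0.51 (miR-146a-5p), and list medians became 0.36 (let-7), 0.73 (miR-200) and 1.59 (colorectal). In pool 2 minus pool 1 media they were -0.25 (miR-29b-3p), -0.47 (miR-22-3p), -0.51 (miR-29c-3p), -0.88 (miR-107), -0.93 (miR-24-3p), -1.18 (miR-130b-3p), -1.59 (miR-423-5p) and -1.71 (miR-320c), and the miR-320 median became -1.89. In pool 3 minus pool 2 media they were 0.13 (miR-194-5p), 0.25 (miR-15b-5p), 0.42 (miR-429), 0.37 (miR-146a-5p), 0.47 (miR-30e-5p), 0.39 (miR-200b-5p) and 0.81 (miR-148a-3p), with medians of 1.24 (miR-17~92), 0.47 (miR-200), 1.35 (colorectal) and 1.60 (miR-26 and miR-30). Relative to the median of all miRNAs, which takes a shared shift out by construction, 0 reversed. These relative values were not tested themselves. The 95 counted as lost there rest on the adjusted p-values of the unshifted total-count test, so they do not show whether calls hold once the shift is removed. Calls numbered 5 (pool 1 exomere minus media), 0 (supermere minus media), 5 (pool 2 minus pool 1 exomere), 170 (pool 2 minus pool 1 media), 41 (pool 3 minus pool 1 media) and 0 (supermere minus exomere). Of 34 list calls 21 held; lost were, in pool 1 exomere minus media, miR-200 (adjusted p 0.0546), miR-26 and miR-30 (0.103) and miR-320 (0.0546); in pool 2 exomere minus media, miR-200 (0.0830), colorectal and miR-320 (both 0.0661); in pool 2 minus pool 1 media, blood (0.0604) and miR-320 (0.342). In pool 3 minus pool 2 media miR-17~92 and miR-26 and miR-30 (both 0.117), miR-200 (0.0806) and colorectal (0.0832) were lost, and in supermere minus exomere miR-200 (0.139).

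limma-voom called 153 (pool 1 exomere minus media), 124 (the same in pool 2), 13 (supermere minus media) and 63 (pool 2 minus pool 1 exomere) miRNAs. For the difference between pools it called 8, DESeq2 5, DESeq2 size factors 2, and 0 passed with the total without the most abundant miRNA, the stricter filter, the additive replicate block or only the groups compared. Omitting both exomere libraries numbered 1 gave 2 there and 14 for pool 2 minus pool 1 exomere.

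With the replicate block nested in the preparation, pool 2 minus pool 1 exomere gave 44 calls, and with the additive block 31. The additive block added the miR-17~92 list in pool 2 minus pool 1 media (0.0445), ended the calls of miR-1290 there and of miR-193a-5p between pools, and changed no other call of a list or named miRNA. Correlations of deviations of same-numbered media libraries were 0.26 and 0.29 (pools 1 and 2), 0.20 and 0.26 (pools 2 and 3) and 0.14 (pools 1 and 3). These were also above the 0.1 set as the minimum. With the nested block these 3 media comparisons gave 96, 132 and 193 calls, against 75, 123 and 182 without a block. Other correlations were -0.12 to 0.02 (pool 2 exomere and media), -0.06 and 0.04 (pool 1), 0.01 and 0.05 (supermere and exomere) and 0.15 (supermere and media). No paired analysis was possible within pool 3 because supermere and media share 1 number.

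An estimated inter-gene correlation ended all 34 list calls. The adjusted p became 0.329 for the 5 lists of pool 1 exomere minus media, 0.377 (let-7, miR-200) and 0.551 (colorectal, miR-320) in pool 2, and 0.286 (let-7, miR-26 and miR-30) and 0.406 (miR-200, colorectal) for pool 2 minus pool 1 exomere. It became 0.192 (let-7, blood, miR-26 and miR-30) and 0.382 (miR-200, colorectal, miR-320) for pool 2 minus pool 1 media. For pool 3 minus pool 2 media it became 0.291 (miR-17~92, miR-200, miR-26 and miR-30, miR-320) and 0.378 (colorectal). For pool 3 minus pool 1 media it became 0.248 (let-7) and 0.224 (the other 6), and for supermere minus exomere 0.237 (miR-17~92) and 0.334 (miR-200, miR-320).

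With 1 library left out, calls ranged from 52 to 116 (pool 1 exomere minus media), 24 to 75 (pool 2), 11 to 26 (supermere minus media), 15 to 32 (pool 2 minus pool 1 exomere), 79 to 131 (pool 3 minus pool 2 media) and 0 to 5 (difference between pools). List adjusted p ranged from 0.0170 to 0.115 (miR-26 and miR-30, pool 1 exomere minus media), 0.00531 to 0.202 (miR-320, pool 2), 0.0326 to 0.507 (let-7) and 0.0149 to 0.836 (other tissues) for supermere minus media. For pool 2 minus pool 1 exomere they were 0.00941 to 0.0709 (miR-200), 0.00306 to 0.0932 (colorectal) and 0.0141 to 0.209 (blood). For pool 2 minus pool 1 media they were 0.0386 to 0.209 (miR-17~92), 0.0365 to 0.0548 (miR-200) and 0.00969 to 0.131 (miR-320), and for pool 3 minus pool 2 media 0.0414 to 0.0877 (miR-26 and miR-30). For pool 3 minus pool 1 media they were 0.00520 to 0.0636 (let-7) and 0.0304 to 0.0600 (blood), and for supermere minus exomere 0.00167 to 0.0710 (miR-200) and 0.0330 to 0.236 (miR-10, miR-99/100 and miR-125).

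Without the most abundant miRNA of each library, the composition means changed by construction. The share of the then most abundant miRNA was 15.9% (pool 1 exomere), 15.4% (pool 1 media), 16.6% (pool 2 exomere), 18.7% (pool 2 media), 15.99% (pool 3 media) and 17.4% (pool 3 supermere), and the top 10 took 64.4%, 49.9%, 70.8%, 63.3%, 72.0% and 79.2%. The effective number was 34.2, 47.6, 26.5, 33.7, 24.4 and 20.1. Mean totals were 334400 (pool 1 media), 313900 (pool 2 media) and 333100 (pool 3 media), and rarefied richness in pool 2 media was 419. The correlation of the exomere-minus-media changes of both pools became 0.757 (Pearson) and 0.770 (Spearman) with the stricter filter.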

Other observations

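The families and arms below were chosen after the data were seen, while the 2 tests on arms were written before their results were seen.

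Pool 1 exomere and pool 2 media, which differ in both name and pool, differed in 16 of 306 miRNAs (6 higher, 10 lower; edgeR, 63 at an unadjusted p under 0.05). The mean Spearman correlation between their libraries was 0.910, against 0.855 between pool 1 exomere and pool 1 media. Of the 4 tested arms of miR-193a and miR-193b, miR-193a-3p rose by log2 2.76 (SE 0.61) and miR-193b-5p by 3.21 (SE 0.61) from media to exomere in pool 1, beside miR-193a-5p and miR-193b-3p (1.64, SE 0.46); in pool 2 the 2 arms rose by 1.22 (SE 0.46) and 1.58 (SE 0.48). In pool 3 supermere against pool 2 exomere, miR-29a-3p, miR-29b-3p and miR-29c-3p were lower by log2 changes of -2.49 (SE 0.47), -1.95 (SE 0.48) and -2.03 (SE 0.48). miR-15a-5p rose (log2 1.41, SE 0.47, adjusted p 0.02) from pool 1 media to exomere, while miR-15b-5p (-2.43) and miR-16-5p (-1.55) fell. In pool 2 miR-15a-5p had a log2 change of 0.04 (SE 0.40, adjusted p 0.968), and miR-15b-5p (-1.55) and miR-16-5p (-2.04) fell.

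Of 57 hairpins with both arms tested, 20 had both arms past the threshold in pool 3 minus pool 1 media, and 18 of these moved in the same direction. The 2 that did not were miR-21 (5p log2 -2.74, SE 0.50; 3p 1.53, SE 0.66, at a mean of 28.5 CPM) and miR-18a (5p -3.73 at 10.2 CPM; 3p 2.77 at 149 CPM). After a GC trend was removed, 2 still had opposite signs. For counting noise, a count of 2 lies between the 0 it would give and the 3 set in advance to exclude it, so arm-specific change cannot be told apart from it. The GC test needed 3 hairpins and only 2 entered it, so it could not have argued against GC content, which stays open.

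The table was also searched for repeated libraries: replicate pairs differed by a chi-square of 60.8 or more per degree of freedom. Besides miR-1246, 4 of the 5 tested miRNAs with an exact match in another annotated small RNA were miR-664a-5p, miR-12136, miR-1291 and miR-6516-3p.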
